A study of Gallus gallus with 8 samples.

How the data were processed

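The series holds 8 Affymetrix chicken genome arrays of total RNA, with 2 arrays in each of 4 groups. The samples are given as hen oocytes at the F1 stage, collected 24 h before ovulation. Per the labels, DPF+ and DPF- are divergently selected lines that differ in fertility, and HG+ and HG- are hens of a single line that differ in fertility. The labels describe the arrays of a group as biological replicates and say nothing more about separate birds or pools. The hens had 14 h of light and 10 h of dark at 20 °C, the RNA amounts in the labels ran from 8.8 to 13.3 µg, and 20 µg of amplified, biotin-labelled RNA is given for each array.

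The deposited values are log2 expression levels per probe set, which the authors made with GCRMA (background correction, normalization between arrays and summary over probes) per the submitters' processing notes, with no version given. Whether all 8 arrays were hybridized and normalized together is not given in the sources used here. The table holds 38535 probe sets. Of these, 96 AFFX control probe sets were left out of the tests, and 8 probe sets with a blank value were left out as well, 6 of them blank on the 4 DPF arrays and 2 on the 4 HG arrays. A probe set was tested when its log2 value was at least 4 on at least 2 of the 8 arrays, which left 12725 probe sets.

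Gene names came from the annotation table given with the series and were looked up by gene identifier in the chicken reference gene table (assembly GCF_016699485.2, bGalGal1.mat.broiler.GRCg7b). On the whole array, 27178 probe sets had 1 gene, 177 had several and 11180 had none. Among the tested probe sets these counts were 10602, 57 and 2066. Gene positions served only to find neighbouring genes.

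The 4 groups were fitted together as group means with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend, two-sided), which left 4 residual degrees of freedom and 3.68 prior degrees of freedom. Adjusted p values are Benjamini-Hochberg values over the 12725 probe sets, with a threshold of 5%. The 4 contrasts were DPF+ against DPF-, HG+ against HG-, the difference between those contrasts, and all DPF arrays against all HG arrays. Changes are log2 differences of group means, positive when the group named first is higher. The number of arrays limits the precision of each of them.

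Gene lists were tested with camera of limma (inter-gene correlation 0.01) on 7048 genes, each represented by its probe set with the highest mean, and the p values were adjusted by Benjamini-Hochberg over the lists of each contrast. The 24 lists were oocyte and germ line, egg coat and gamete membrane, granulosa cell markers, steroidogenesis, theca with stroma and extracellular matrix, red blood cells, leukocytes, endothelium, liver and yolk precursor proteins, oviduct and egg white proteins, M phase and meiotic division, DNA replication, apoptosis, heat shock and chaperones, immediate early genes, TGF-beta and BMP signalling, WNT signalling, interferon response, major histocompatibility complex and antigen presentation, cholesterol synthesis and uptake, oxidative phosphorylation, ribosomal proteins, proteasome, and glycolysis. Lists with fewer than 5 measured genes were not tested, which left 20. Some list names reached a measured gene only through a synonym in the reference table. Among the genes named in the report this holds for BIRC8, PGK2 and MHCY4, which stand where the lists had XIAP, PGK1 and YF6. The lists, the contrasts, the tests, the alternatives that are not described as added later and the rule for naming genes were fixed before the data were examined.

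The rule named, among probe sets past 5% with a single gene name and no overlap of the arrays compared, the 10 with the largest rise and the 10 with the largest fall. Where fewer than 5 passed in a direction, it named up to 8 per direction with the smallest unadjusted p among those with an absolute log2 change of at least 1 and no overlap of arrays. It added every called member of each list, or up to 2 with the smallest p where none was called, and the 10 smallest p of the difference between the contrasts. It ranked by the fitted changes. Where the mean of 1 of the groups compared was under 4, the report gives the change counted from 4 in its place, as a bound, a choice made after the values were seen. The report leaves out ALAS1, which stood for ALAS2 in the red blood cell list, and names the list members without a call only for part of the lists. The genes of high level in the opening of the report were chosen after their values were seen.

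The alternatives were no filter and a stricter filter at a log2 value of 6, median centring and quantile normalization, eBayes without a trend, robust eBayes, no moderation, 1 common variance for all probe sets (without the 1% of smallest and the 1% of largest variances), only the 4 arrays of a contrast, the replicate number as a block, the RNA amount as a covariate, array weights, a 2-group model for DPF against HG, and each array left out in turn. For lists they were an estimated inter-gene correlation, fry, no filter, quantile normalization, the block, the mean of all probe sets of a gene, and each array left out. The 3' minus 5' difference of control transcripts as a covariate and the crossed replicate numbers were added after seeing the data. The 3' minus 5' difference is that of the actin, GAPDH and EF1a control probe sets of an array, and their mean.

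The steps were tested on simulated data with changes put into 12725 simulated probe sets. For DPF+ against DPF-, 75% of log2 changes of 2 and 15% of log2 changes of 1 were recovered, with 2 false calls. For DPF against HG arrays, 93% and 56% were recovered, with 9 false calls. A ribosomal protein list shifted by 0.3 among 7048 simulated genes was found by camera with an adjusted p of 6.73e-16, and 0 other lists were called. The simulated genes varied independently of each other and with the same spread in all groups. In the data the estimated inter-gene correlation of that list was 0.394. The SD of the difference between replicates was 0.746 in DPF+ and 0.276 in HG+. The simulated rates may therefore not hold for the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.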

Results

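Expression was measured in samples given as hen oocytes 24 h before ovulation, on 8 arrays, 2 for each of the groups DPF+, DPF-, HG+ and HG-. Between 11433 and 12092 probe sets per array reached a log2 value of at least 4, and the array medians over all probe sets lay between 2.76 and 2.79. A group mean under 4 is not taken as above background, so a change against it is counted from 4 and given as a bound ("or more", "or lower"). Of the 13 egg coat genes 7 passed the filter, with means over the 8 arrays from 13.95 for ZP3, which avian granulosa cells make, down to 5.77 for CD81. Of the 27 granulosa markers 19 passed, down to a mean of 4.67 for RGN. Of these HSD3B1, a steroid dehydrogenase, averaged 12.13, the luteinizing hormone receptor LHCGR 11.50, and the ovarian transcription factor FOXL2 11.04. With granulosa markers at such levels, the values below cannot be taken as those of the oocyte alone. CCNB1, the cyclin that drives entry into M phase, averaged 13.54, and the germ cell RNA-binding gene DAZL 7.38. Of the 10 oviduct and egg white genes on the array 0 passed the filter, and of the 24 leukocyte genes 2 did, CD74 (mean 8.54) and, through a synonym, LSP1P1 (mean 4.52).

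The HG arrays of a group were close to each other and the DPF+ arrays were not. The SD of the difference between replicates over the tested probe sets was 0.746 in DPF+, 0.456 in DPF-, 0.282 in HG- and 0.276 in HG+. The HG arrays did not group by fertility. Each correlated slightly more closely with an array of the other HG group than with its own replicate. HG- replicate 1, for example, had r = 0.993 with HG+ replicate 2 and r = 0.989 with HG- replicate 2. DPF+ replicate 1 correlated more closely with DPF- replicate 2 (r = 0.977 across probe sets, which are not independent replicates) than with DPF+ replicate 2 (r = 0.927), while DPF- replicate 1 was closer to DPF- replicate 2 (r = 0.972) than to DPF+ replicate 2 (r = 0.961). The split showed in cell division genes. The median of the 38 M phase genes, relative to the mean of the 8 arrays, was -0.56 in DPF+ replicate 1 and -0.50 in DPF- replicate 2, but 0.42 in DPF+ replicate 2 and 0.07 in DPF- replicate 1. The 21 cholesterol synthesis genes went the other way, at 0.41 and 0.22 against -0.31 and -0.07. RLN3, a relaxin family hormone, divided the same arrays, with 12.73 in DPF+ replicate 1 and 12.65 in DPF- replicate 2 against 10.06 in DPF+ replicate 2 and 9.68 in DPF- replicate 1. The 3' probe sets of control transcripts exceeded the 5' probe sets by 1.84 ± 0.03 (log2, SD, n = 2) in DPF+, 1.44 ± 0.15 in DPF-, 1.16 ± 0.01 in HG+ and 1.07 ± 0.04 in HG-. The mean was 1.64 ± 0.25 (SD, n = 4) on the DPF arrays and 1.12 ± 0.06 on the HG arrays, a difference of 0.522 (exact two-sided permutation p = 0.0286, the smallest that the 70 splits can give).

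**Figure D1:**
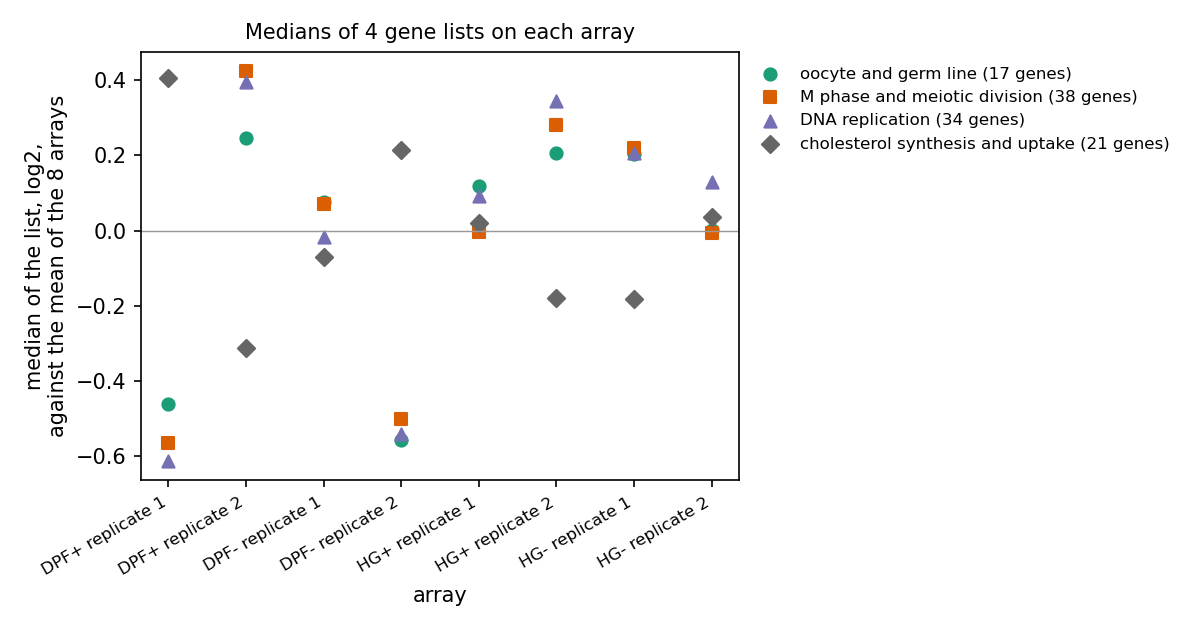
Median log2 level of 4 gene lists on each of the 8 arrays, relative to the mean of the 8 arrays (points, 1 per list and array). The M phase median was -0.56 in DPF+ replicate 1 and -0.50 in DPF- replicate 2, and 0.42 in DPF+ replicate 2, while the cholesterol list was 0.41, 0.22 and -0.31 on the same arrays.

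**Figure D2:**
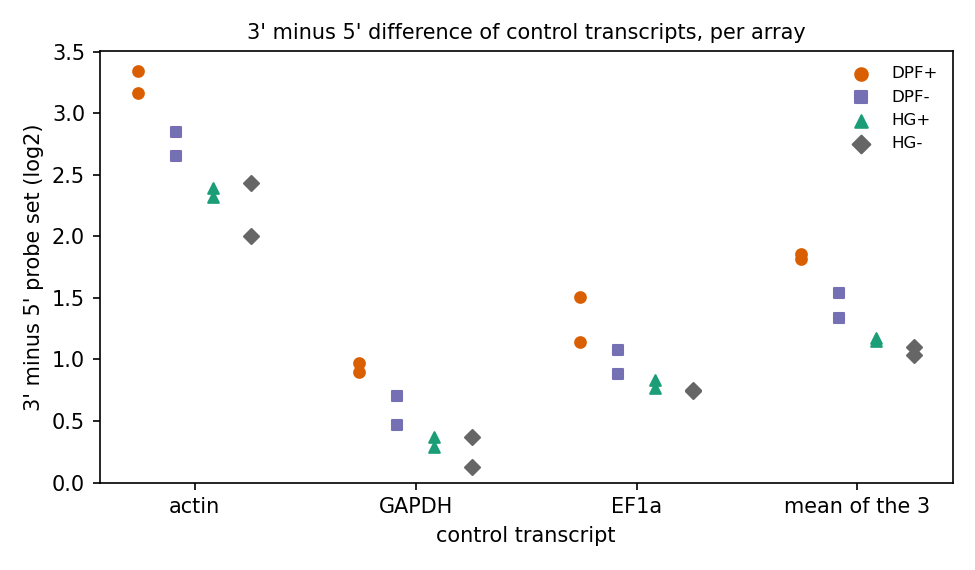
Log2 difference between the 3' and 5' probe sets of 3 control transcripts and their mean, 1 point per array and transcript. The mean lay between 1.33 and 1.86 on the DPF arrays and between 1.04 and 1.17 on the HG arrays.

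DPF+ and DPF- were compared to ask which genes differ between lines selected in opposite directions. No gene passed the test, and the values below are those of the smallest p. Antigen presentation and interferon genes were lower in DPF+ as groups by camera, but not called with an estimated correlation (adjusted p = 0.963 for each) or with fry (adjusted p = 0.881 for each). TAPBP, the chaperone that loads peptides onto class I molecules, had a mean of 3.91 ± 0.62 (SD, n = 2) in DPF+ and 6.17 ± 0.55 in DPF- (log2 change -2.17 or lower), and BF2, a class I heavy chain of the chicken, had 4.60 ± 0.26 and 5.67 ± 0.07 (log2 change -1.07). The interferon-induced genes LY6E (log2 change -1.91 or lower) and PARP9 (-0.56 or lower) had the lowest p of their list. Single arrays moved both. The fitted change of LY6E was -2.36, but -1.62 without DPF- replicate 1 and -3.10 without DPF- replicate 2. That of PARP9 was -0.82, but -0.545 without DPF+ replicate 2 and -1.095 without DPF+ replicate 1. The plasma apolipoproteins APOH (-1.45) and APOA1 (-0.76, but -0.30 without DPF+ replicate 2 and -1.23 without DPF+ replicate 1) were the members of the liver and yolk precursor list with the smallest p.

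By camera 4 lists fell in DPF+, and each had an adjusted p = 0.963 with an estimated correlation and 0.881 with fry. The ribosomal proteins fell with a median of -0.10 (47 of 62 genes negative, adjusted p = 0.0102), with RPL7A at -0.50 (-0.21 without DPF- replicate 2, -0.79 without DPF- replicate 1) and RPL21 at -0.50 (-0.16 without DPF+ replicate 2, -0.84 without DPF+ replicate 1). The liver and yolk precursor list fell with a median of -0.76 (4 of 5 negative, adjusted p = 0.0173), the antigen presentation list with a median of -0.26 (10 of 14 negative, adjusted p = 0.0173), and the interferon list with a median of -0.11 (9 of 13 negative, adjusted p = 0.0403). Adjusted over the list alone, 1 liver gene, 2 antigen presentation genes and 3 interferon genes passed as lower, and over all genes 0 did. Each call depended on single arrays. Without DPF+ replicate 2 the adjusted p was 0.725 for the ribosomal and the liver list, 0.749 for antigen presentation and 0.129 for interferon. Without DPF- replicate 2 it was 0.540 for the ribosomal list, whose direction turned, and 0.540 for antigen presentation, and the interferon list had 0.409 without DPF- replicate 1 and 0.316 without DPF+ replicate 1. Without the filter the liver list (adjusted p = 0.616) and antigen presentation (0.399) lost the call, and with the mean of all probe sets of a gene the interferon list did (0.0504). The 3' minus 5' difference was also larger in DPF+ than in DPF-, 1.84 against 1.44.

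Among single genes, EXOSC1, a subunit of the RNA exosome, was at 6.33 ± 1.07 in DPF+ and 3.31 ± 0.34 in DPF- (log2 change 2.33 or more, limma adjusted p = 0.196). CSNK1E, a casein kinase of the circadian clock and of WNT signalling, had a log2 change of 1.57 or more (adjusted p = 0.196). Other genes with higher values in DPF+ were FAM132A (1.68), the membrane peptidase MME (1.40), the trafficking gene TRAPPC10 (1.32), the receptor activity modifier RAMP3 (1.31), the cyclin CCNJ (0.75 or more) and POLA2, a subunit of DNA polymerase alpha (0.55 or more). RFX3, a transcription factor of ciliated cells, was at 4.85 ± 0.28 in DPF+ and 7.10 ± 0.50 in DPF- (log2 change -2.26, adjusted p = 0.171). CRIP1, a LIM domain protein, was at 7.89 ± 0.31 and 9.99 ± 0.14 (log2 change -2.10, adjusted p = 0.171). Other genes with lower values were VWC2, a BMP antagonist (-2.39), the B-G gene BG8 of the chicken major histocompatibility complex (-1.48), HOXA6 (-0.68 or lower), the semaphorin SEMA5A (-1.34 or lower), TAB3, an adaptor of NF-kappa-B signalling (-1.37), and ZNF207, a kinetochore protein (-1.14). The rule named only genes in which both DPF+ arrays lay on the same side of both DPF- arrays. Among the other probe sets of these genes, 1 of the 4 of ZNF207 went the other way.

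**Figure D3:**
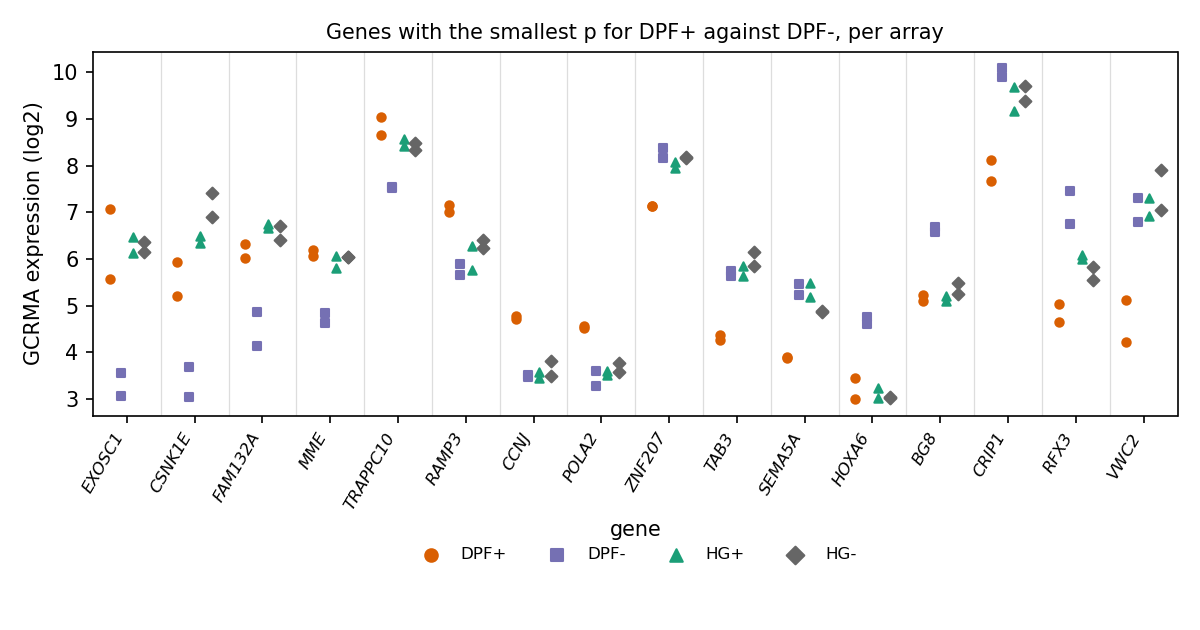
Log2 expression of the 16 named genes with the smallest p for DPF+ against DPF-, 1 point per array, with the HG arrays beside them. EXOSC1 averaged 6.33 in DPF+ and 3.31 in DPF-, and RFX3 4.85 and 7.10.

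The ovarian lists did not pass. The granulosa markers had a median of -0.11 (11 of 19 negative, adjusted p = 0.200), with the transcription factor GATA4 at -0.76 and the activin-binding protein FST at 0.51 (0.21 without DPF+ replicate 2, 0.81 without DPF+ replicate 1). The 20 steroidogenesis genes had a median of 0.02, a mean of -0.06 and a test pointing down (adjusted p = 0.579). Of these, the electron carrier FDX1 was at 0.38 (0.16 without DPF+ replicate 2, 0.61 without DPF+ replicate 1) and the side chain cleavage enzyme CYP11A1 at -0.64, which was 0.07 without DPF+ replicate 2 and -1.34 without DPF+ replicate 1. The oocyte list had a median of 0.12 (12 of 17 positive, adjusted p = 0.579), with the oocyte linker histone H1FOO at 0.46 (0.04 without DPF- replicate 2, 0.88 without DPF- replicate 1) and the egg nucleoplasmin NPM2 at 0.37 (0.07 without DPF+ replicate 2, 0.67 without DPF+ replicate 1). The egg coat list had a median of -0.08 but a mean of 0.07 (7 genes, adjusted p = 0.963). M phase genes had a median of 0.14 (29 of 38 positive, adjusted p = 0.248), with the kinetochore genes CENPF at 1.25 (0.65 without DPF+ replicate 2) and NUF2 at 1.00 (0.29 without DPF- replicate 2, 1.71 without DPF- replicate 1), and DNA replication genes 0.17 (25 of 34 positive, adjusted p = 0.248). With all arrays the estimated inter-gene correlation was 0.786 for M phase and 0.666 for DNA replication, far above the 0.01 that camera was given. With it the adjusted p was 0.963 for each. The direction of the M phase and DNA replication lists turned with single arrays. Without DPF+ replicate 1 camera called M phase (adjusted p = 0.000466) and DNA replication (0.000434) as higher and granulosa markers as lower (0.0222). Without DPF- replicate 1 M phase (0.000691), DNA replication (0.00794) and the oocyte list (0.0413) were called as higher. Without DPF+ replicate 2, in contrast, M phase (0.0170) and DNA replication (0.0155) were called as lower.

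The median of the immediate early genes was 0.28 (adjusted p = 0.455), that of TGF-beta and BMP signalling 0.11 (adjusted p = 0.579), with ID3, a target of BMP signals, at 1.09, and that of WNT signalling -0.05 (adjusted p = 0.455). Oxidative phosphorylation had a median of -0.08 (41 of 58 negative, adjusted p = 0.0668), cholesterol synthesis -0.15 (adjusted p = 0.579), and glycolysis -0.15 (adjusted p = 0.248), with lactate dehydrogenase LDHA at -0.97. Cholesterol synthesis was called as lower without DPF+ replicate 1 (adjusted p = 0.00168) and as higher without DPF+ replicate 2 (0.00644). Oxidative phosphorylation was called as lower without DPF- replicate 1 (0.000117) or DPF+ replicate 1 (0.0197) and with quantile normalization (0.0485), and glycolysis as lower without DPF+ replicate 1 (0.0207). The median was 0.05 for apoptosis (adjusted p = 0.958), 0.01 for theca and stroma (adjusted p = 0.974), and 0.01 for the proteasome, where mean and test pointed down (adjusted p = 0.579). Heat shock genes had a median of 0.01 and a mean of 0.03 with a test pointing down (adjusted p = 0.958). Adjusted over the list alone, 1 gene each of DNA replication, WNT signalling and red blood cells passed as higher. The lists too small to test had medians of 0.38 for red blood cells (3 genes), 0.11 for leukocytes (2 genes) and 0.07 for endothelium (4 genes).

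Of the 12725 probe sets, 0 passed 5% in limma for DPF+ against DPF-, with a smallest adjusted p of 0.171. At an unadjusted p under 0.05 there were 781, 334 higher and 447 lower, where 636.25 are expected by chance. The count was 801 with median centring, 764 with quantile normalization, 795 without the intensity trend, 754 with robust variance, 840 without moderation and 682 with the RNA amount as a covariate. This fit shares 1 variance per probe set with the less variable HG arrays, which can make its p values for the DPF contrast too small. The count was below that of chance with only the 4 DPF arrays (297, smallest limma adjusted p 0.9998). It was also below with array weights (245) and with the replicate number as a block (592). Leaving out an array gave 4253 (DPF+ replicate 1), 1772 (DPF+ replicate 2), 890 (DPF- replicate 1), 553 (DPF- replicate 2), 519 (either HG- array) or 509 (either HG+ array). The groups did not overlap in 23.3% of probe sets, against 33.3% by chance. Other settings gave 10 calls without the filter and 87 with 1 common variance. Leaving out DPF+ replicate 1 gave 1070 calls and leaving out DPF+ replicate 2 gave 2, and of the 1070 probe sets 48.2% had the same sign in both fits.

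HG+ and HG- were compared to ask which genes differ with fertility within a single line. Differences were small, and no gene passed. As groups, oxidative phosphorylation genes were lower in HG+ and immediate early genes higher by camera, but each had an adjusted p = 0.957 with an estimated correlation and 0.950 with fry. The oxidative phosphorylation list fell with a median of -0.10 (48 of 58 negative, camera adjusted p = 0.00819), with NDUFB5 of complex I at -0.40 and COX7C of cytochrome c oxidase at -0.19. The immediate early list rose with a median of 0.06 (15 of 19 positive, adjusted p = 0.0468), with the transcription factor EGR1 at 0.84 and CCN2, a matricellular growth factor, at 0.29. Adjusted over the list alone 0 genes passed in either list. The mean 3' minus 5' difference was larger in HG+ than in HG-, 1.16 against 1.07, with no overlap of the arrays (1.15 and 1.17 against 1.04 and 1.10). Of the single transcripts, actin and GAPDH overlapped and EF1a did not. With 2 arrays per group, no overlap arises in 33.3% of cases by chance. Oxidative phosphorylation lost the call without HG- replicate 1 (adjusted p = 0.136) or HG+ replicate 2 (0.503). The immediate early list lost it without HG- replicate 1 (0.547), HG+ replicate 1 (0.118), HG+ replicate 2 (0.219), DPF+ replicate 1 (0.0736) or DPF+ replicate 2 (0.0721), and without the filter (0.391).

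The single genes with the smallest p were AGA, a lysosomal enzyme that degrades glycoproteins (log2 change 1.75, from 5.72 in HG- to 7.47 in HG+), GTSF1, a germ cell gene of the piRNA pathway (1.10), ARPP21 (-0.57 or lower), and LIN52, a subunit of the DREAM cell cycle complex (-1.55). Their limma adjusted p was 1, and the 2 other probe sets of AGA went the other way. As the rule required, both HG+ arrays lay on the same side of both HG- arrays. Among list members with the smallest p, MHCY4 of the antigen presentation list was at -0.98, BF2 lay under 4 in both groups, and of the apoptosis list the death receptor FAS was at 0.63 and the survival factor MCL1 at -0.51. Of the granulosa and steroid genes, anti-Müllerian hormone AMH was at -0.20, RGN at -0.18, the estrogen-forming HSD17B1 at 0.46 and the cholesterol transporter NPC1 at -0.17, where AMH and NPC1 each had 1 other probe set of the opposite sign. Of the oocyte and egg coat genes, TDRD7 was at 0.24, CNOT6L at -0.24, ZP2 at -0.15 and the integrin ITGA6 at -0.31. A single array moved most of these list members by over 1.5 times. AMH was at -0.01 and RGN at -0.01 without HG+ replicate 1, and -0.40 and -0.34 without HG+ replicate 2. HSD17B1 ran from 0.21 without HG- replicate 2 to 0.72 without HG- replicate 1, FAS from 0.29 without HG- replicate 1 to 0.98 without HG- replicate 2, and MCL1 was at -0.26 without HG+ replicate 2. TDRD7 was at 0.11 and NPC1 at -0.09 without HG- replicate 2, and ZP2 at -0.08 without HG+ replicate 1. In the stroma list COL1A2, a fibrillar collagen chain, was at 0.64 (0.39 without HG- replicate 1) and the smooth muscle kinase MYLK at -0.38, and of the chaperones HSPB8 was at -0.86 and DNAJA2 at -0.27, which were -0.29 and -0.10 without HG- replicate 2 and -1.44 and -0.43 without HG- replicate 1. The smallest adjusted p among the other 18 lists was 0.0568, for the ribosomal proteins (median -0.08, 48 of 62 negative). That list was called as lower without the filter (0.0129), with quantile normalization (0.0352) and without HG+ replicate 1 (0.000471), DPF- replicate 1 (0.0352) or DPF- replicate 2 (0.0356). Without HG+ replicate 1 camera also called M phase (0.00131) and DNA replication (0.00535) as higher, and TGF-beta and BMP signalling (0.00493), antigen presentation (0.000471) and cholesterol synthesis (0.0142) as lower.

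Of the 12725 probe sets, 0 passed 5% in limma for HG+ against HG-, with a smallest adjusted p of 1. At an unadjusted p under 0.05 there were 45, 18 higher and 27 lower, against 636.25 expected by chance. The fit shares 1 variance per probe set with the more variable DPF arrays, and the count was 298 with only the 4 HG arrays, 213 with the RNA amount as a covariate, 129 without moderation, and 349 with array weights (smallest adjusted p 0.0620). It was 128 without DPF+ replicate 1, 129 without DPF+ replicate 2, 83 without HG- replicate 1 and 26 without HG+ replicate 2. The groups did not overlap in 25.1% of probe sets, against 33.3% by chance. Without the filter 1 probe set was called and with 1 common variance 4 were.

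The design asks whether the genes linked to fertility differ between lines and within a line. The changes in the DPF and HG contrasts were nearly unrelated across probe sets, which are not independent replicates (Pearson r = 0.0354, Spearman rho = 0.0384), and 51.2% of probe sets had the same direction in both. At an unadjusted p under 0.05, 5 probe sets were higher in both where 0.472 are expected (one-sided Fisher exact p = 7.82e-05), and 2 were lower in both where 0.948 are expected (p = 0.245). In opposite directions there were 3 where 1.34 are expected. The 2 contrasts share 1 variance per probe set, which can make small p coincide in either direction and which the Fisher test leaves out. The correlation ran from -0.103 without HG+ replicate 2 to 0.160 without HG+ replicate 1.

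The genes with the smallest p for a difference between the contrasts had, apart from AGA, the larger change in the DPF contrast. RFX3 differed by -2.61, with -2.26 for DPF+ against DPF-, CRIP1 by -1.98, MME by 1.52 and RAMP3 by 1.61. AGA differed by -2.50, with 1.75 for HG+ against HG-. SEMA5A and HOXA6 had negative and CSNK1E, CCNJ and CCDC43 positive differences, for which no size is given, since a DPF group mean was under 4 in each and both HG means in HOXA6 and CCNJ. The limma adjusted p of the 10 genes ran from 0.893 to 0.999. Of 12725 probe sets 0 passed, 364 had an unadjusted p under 0.05, and 1 passed without the filter and 21 with 1 common variance. The 364 became 2701 without DPF+ replicate 1, 1163 without DPF+ replicate 2, 202 without HG- replicate 2, 212 without HG- replicate 1, 167 without HG+ replicate 1 and 210 without HG+ replicate 2. No list passed (smallest adjusted p 0.0575, for the liver and the interferon list, and 0.918 with an estimated correlation), though 8 did without DPF+ replicate 1, 6 without DPF- replicate 1, 3 without DPF+ replicate 2 or HG+ replicate 2 and 1 without DPF- replicate 2.

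The DPF and HG arrays were compared as a scale for the other contrasts, since the source of the hens differs between them. Single genes such as COL1A2 and FABP3 fell on the DPF arrays, and others such as RLN3 and FN1 rose. COL1A2 averaged 4.81 ± 0.82 (SD, n = 4) on the DPF arrays and 8.58 ± 0.42 on the HG arrays (log2 change -3.77, limma adjusted p = 0.00133). NID1, a basement membrane protein, had 2.84 ± 0.37 and 5.55 ± 0.16 (log2 change -1.55 or lower, adjusted p = 0.0012), and its other 3 probe sets went the same way. DPF3, a chromatin reader of the BAF complex whose name only resembles the line's, had 7.49 ± 1.07 and 2.65 ± 0.22 (log2 change 3.49 or more, adjusted p = 0.00287), but its other probe set went the other way.

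Genes higher on the DPF arrays included the solute carrier SLC35F2 (log2 change 3.75 or more), RLN3 (3.29, at 11.28 ± 1.64 against 7.99 ± 0.08), the selenoprotein SELENOP1 (2.86 or more), NUFIP2 (2.32 or more), the phospholipase PLCG1 (2.14), GLIPR2 (2.06), the splicing factor RBFOX2 (2.06) and the endosomal adaptor APPL2 (1.95 or more, its other probe set the other way). Genes lower on the DPF arrays included the betaine-homocysteine methyltransferase BHMT2 (-2.67), MYO10L (-2.45 or lower), the fatty acid carrier FABP3 (-2.32), CSNK1E (-2.32), the corepressor CBFA2T3 (-1.83 or lower), APOH (-2.16) and the clathrin adaptor subunit AP2B1 (-1.20 or lower). DIEXF, a nucleolar protein, was called both ways, with 2.82 or more on one probe set and -1.12 or lower on another. As the rule required, all 4 DPF arrays lay on one side of all 4 HG arrays in each of these genes. Their limma adjusted p ran from 0.00101 for NUFIP2 to 0.0418 for PLCG1. NUFIP2 and CBFA2T3 each had 2 other probe sets, 1 of them the other way.

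**Figure D4:**
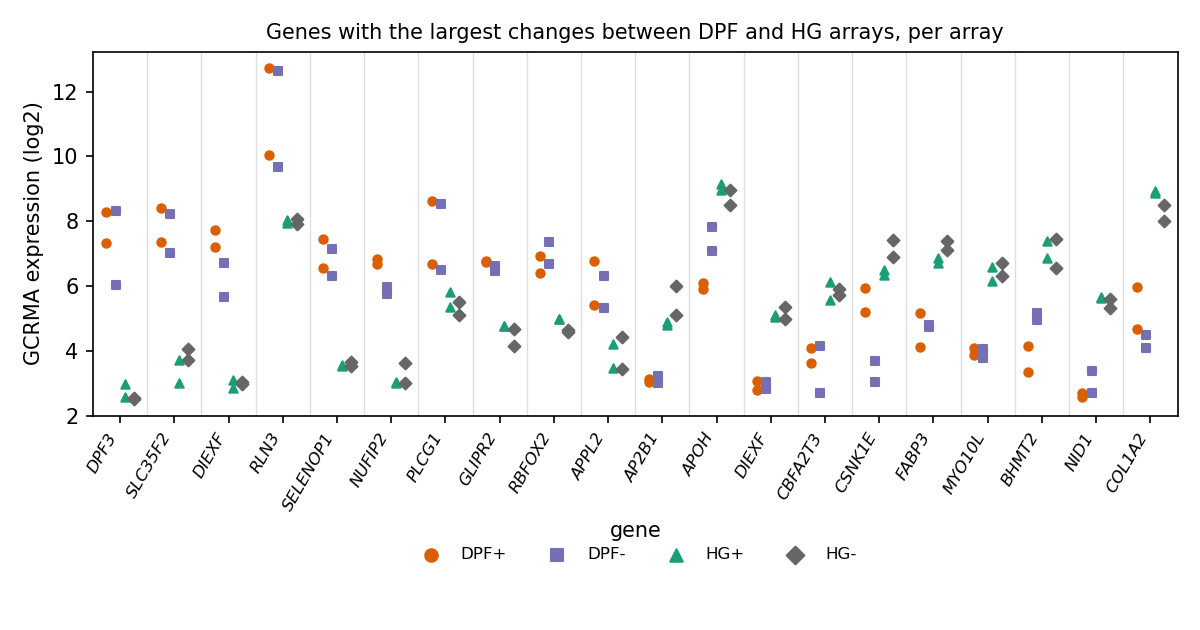
Log2 expression of the probe sets with the 10 largest fitted rises and the 10 largest fitted falls between DPF and HG arrays, 1 point per array, several of them against a group mean under 4. COL1A2 averaged 4.81 on the DPF and 8.58 on the HG arrays, and RLN3 11.28 and 7.99.

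The DNA replication list fell on the DPF arrays with a median of -0.39 (30 of 34 negative, camera adjusted p = 0.00817), but had an adjusted p = 0.938 with an estimated correlation and 0.499 with fry. Of its members 5 fell past 5%, both over all genes and adjusted over the list alone. These were the replication factor MCM10 (-1.11 or lower), the ligase LIG1 (-0.45 or lower) and the clamp loader subunit RFC1 (-0.88). The others were the polymerase subunit POLA1 (-0.85) and the ribonucleotide reductase RRM1 (-0.76). The list had an adjusted p of 0.0685 with the mean of all probe sets of a gene and 0.246 without DPF+ replicate 1. The RNA of the DPF arrays had the larger 3' minus 5' difference, 1.64 against 1.12, and the 4 DPF arrays did not lie on one side of the HG arrays in this list. Its median was -0.61 in DPF+ replicate 1, -0.54 in DPF- replicate 2 and -0.02 in DPF- replicate 1, but 0.39 in DPF+ replicate 2, above the highest HG array (0.35).

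No other list passed, and the smallest adjusted p among them was 0.197, for oxidative phosphorylation (median -0.16, 48 of 58 negative). That list was called as lower without the filter (0.00011), with quantile normalization (0.0452) and without DPF- replicate 2 (0.00238) or DPF+ replicate 1 (0.0167). The ribosomal proteins were called as lower without the filter (0.0053) or DPF- replicate 2 (0.00225), the chaperones as lower without the filter (0.0467), and M phase as lower without DPF- replicate 1 (0.0373) or DPF+ replicate 2 (0.00486). Cholesterol synthesis was called as higher without DPF+ replicate 2 (0.0103). Single members still did. In the matrix list, which was not called (adjusted p = 0.453), fibronectin FN1 rose (0.94) while COL1A2, NID1 and MYLK (-1.21) fell. In TGF-beta and BMP signalling 3 of 30 genes rose, FSTL4 (1.45 or more) and the BMP targets ID1 (0.73) and ID2 (0.59). BF2 (1.14 or more) and LY6E (0.73 or more) rose, and PARP12 (-0.86) and TRIM41 (-0.14 or lower) of the same lists fell. The bounds of LY6E and TRIM41 rest on means near 4, at 4.73 on the DPF and 4.135 on the HG arrays. With an array left out the fitted change ran from 1.0075 to 1.7475 for LY6E and from -1.3275 to -0.8275 for TRIM41. In steroidogenesis the mitochondrial cholesterol-binding protein TSPO (-0.88) and the reductase AKR1D1 (-1.34) fell, and among the granulosa markers GATA4 did (-0.64). In apoptosis FAS (-0.98), the nuclease ENDOG (-1.25) and BIRC8 (-0.77) fell, and among chaperones HSPA4 (-0.56) and HSPB8 (-0.66 or lower). EGR1 (-1.03), the WNT target AXIN2 (-0.64), PGK2 of glycolysis (-0.69), PMVK of cholesterol synthesis (-0.70) and the endothelial cadherin CDH5 (-0.03 or lower) fell as well. Adjusted over the list alone, 2 matrix genes rose and 3 fell, 2 antigen presentation genes rose and 1 fell, and 0 granulosa, chaperone or cholesterol genes passed.

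In all, 1588 probe sets of 1143 genes passed 5% in limma, 443 higher and 1145 lower on the DPF arrays, with a smallest adjusted p of 0.000763. Probe sets from predicted transcripts gave 606 lower and 115 higher calls, and those from cDNA 539 lower and 327 higher. Among the genes named as lower, COL1A2, BHMT2, AP2B1, MCM10, LIG1 and POLA1 had probe sets from predicted transcripts. FABP3, CSNK1E, APOH, RFC1 and RRM1 had probe sets from cDNA. All 4 DPF arrays lay on one side of all 4 HG arrays in 24.8% of probe sets, against 2.86% by chance. With quantile normalization the split was 627 higher and 803 lower. The count was 0 with the 3' minus 5' difference as a covariate, an alternative chosen after seeing the data. This covariate correlated with the source of the hens at 0.860, and the median SE of the 1588 rose from 0.172 to 0.769. The fit therefore cannot separate the 3' minus 5' difference from the source. Leaving out an array gave 174 (HG- replicate 2), 250 (HG+ replicate 2), 311 (HG- replicate 1), 346 (HG+ replicate 1), 518 (DPF- replicate 2), 1019 (DPF- replicate 1), 2624 (DPF+ replicate 1) or 4846 (DPF+ replicate 2).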

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

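Each group holds only 2 arrays, which is too few to test whether an array lies apart from its group. The test of the difference between the DPF and HG contrasts called 0 probe sets in limma (364 at an unadjusted p under 0.05), so no result of this kind is listed.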

How the results depend on the processing

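The crossed replicate numbers and the 3' minus 5' covariate were chosen after seeing the data. The covariate correlated with the source of the hens at 0.860, so calls lost or signs turned with it do not show its effect apart from the source. Where an array is left out, the lone array of its group is assumed to vary like the other groups. The cause of a change was not tested unless stated. For DPF+ against DPF- (0 calls) the count was 10 without the filter, all of them probe sets below it, 87 with 1 common variance, and 0 to 1070 with an array left out, where the 2 calls without DPF+ replicate 2 are probe sets without a gene name. For HG+ against HG- (0) it was 1 without the filter, a probe set without a gene name, and 4 with 1 common variance, among them AGA and LIN52, and 0 whichever array was left out. For the difference (0) it was 1 without the filter, KCNMB1, 21 with 1 common variance, and 0 whichever array was left out. The genes named here were chosen after their values were seen. For DPF against HG (1588) the count was 1045 without the filter, 549 with the stricter filter, which tests fewer probe sets, 574 without moderation, 2384 with 1 common variance, 0 with the 3' minus 5' covariate, and 174 to 4846 with an array left out. The split of 443 higher and 1145 lower was 627 and 803 with quantile normalization. Replicate numbers do not pair the samples by the labels. Same-numbered arrays deviated with a correlation of -0.521 in the DPF groups and -0.194 in the HG groups. It was 0.507 for DPF+ with HG+, 0.116 for DPF- with HG-, -0.255 for DPF+ with HG- and -0.429 for DPF- with HG+. With the replicate number as a block DPF against HG had 870 calls, 863 of them shared, the lists called for the difference were 2, liver and interferon (adjusted p = 0.0434 each), and the block moved no other count of calls by over 1.5 times. With crossed numbers there were 3 calls for DPF+ against DPF- and 2677 for DPF against HG. The alternatives not named so far kept the 3 counts of 0 and gave 1202 to 2228 calls for DPF against HG. The correlation of the 2 contrasts (0.0354) was 0.0162 without the filter, 0.0775 with the stricter filter, and -0.103 to 0.160 with an array left out. The lists called for DPF+ against DPF- (4) were 0 with an estimated correlation, 0 with fry, 2 without the filter and 2 to 9 with an array left out. For HG+ against HG- (2) they were 0 with an estimated correlation, 0 with fry and 0 to 7 with an array left out. For the difference (0) they were 0 to 8 with an array left out. For DPF against HG (1) they were 0 with an estimated correlation, 0 with fry, 0 with the mean of all probe sets, 4 without the filter, 2 with quantile normalization and 1 to 3 with an array left out. The called lists kept their sign of the median under median centring and quantile normalization, though the ribosomal median in DPF+ against DPF- went from -0.10 to -0.0514 with quantile normalization. Among the named genes the sign turned for few. With the 3' minus 5' covariate, in DPF+ against DPF-, NPM2 was at -0.38, H1FOO at -1.12, FST at -0.10, CYP11A1 at 1.28, APOA1 at 0.76, NUF2 at -1.58, RPL7A at 0.74 and RPL21 at 0.75, HSD17B1 in HG+ against HG- at -0.0704, and in DPF against HG MYLK at 0.0246 and LY6E at -1.78. With the RNA amount as a covariate CNOT6L was at 0.0398, ZP2 at 0.10 and AMH at 0.0836 in HG+ against HG-. CYP11A1 in DPF+ against DPF- ran from -1.34 to 0.07 with an array left out. Of the 48 probe sets named as past 5% in DPF against HG, 46 lost the call with their sign kept under the 3' minus 5' covariate, besides MYLK and LY6E. The call was lost in 18 with the block, 8 with quantile normalization and 1 with robust variance. On each array 29.7 to 31.5% of probe sets reached the filter, and signal near background limits the rest.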

Other observations

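The 3 tests of the split between replicates were chosen only after the split was seen, as were the 3' minus 5' covariate and the relations between lists. The median of the 17 oocyte genes went with that of the 38 M phase genes (r = 0.966, exact permutation p = 0.00067, Spearman rho = 0.952, exact p = 0.00114; both lists hold CCNB3 and MOS) and with that of the 34 DNA replication genes (r = 0.967, exact permutation p = 0.00186, rho = 0.905, exact p = 0.00456). The M phase median ran against that of the 21 cholesterol genes (r = -0.978, exact permutation p = 7.44e-05, rho = -0.976, exact p = 0.000397). These 3 relations were picked from the 190 pairs of the 20 lists. Over the 190 the Benjamini-Hochberg adjusted p was 0.0365, 0.0525 and 0.0141 for r and 0.0867, 0.0867 and 0.0754 for rho, and 4 pairs passed 5% by r and 0 by rho. Without DPF- replicate 2 and DPF+ replicate 1 r was 0.892, 0.784 and -0.987.

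The arrays of DPF+ and of DPF- split in these lists. An unequal share of oocyte or dividing cells between the samples could give the correlation of 0.966 between oocyte and M phase genes, but the lists were picked because they showed the split, so this decides nothing, and a difference between birds could give the same. An unequal 3' bias of the RNA within the groups was tested with the control transcripts, and for 1 of 3 the array with the higher M phase median differed the same way in both DPF groups, which decides nothing. Labels exchanged between a DPF+ and a DPF- array would leave the partner out of place too. DPF- replicate 1 correlated less closely with DPF+ replicate 2 (r = 0.961 across probe sets, which are not independent replicates) than with any other array. It had 0.972 with DPF- replicate 2. The next lowest was HG- replicate 2 (0.962), and the gap to that array is too small to exclude an exchange. Such an exchange would change every value of DPF+ against DPF-, and it stays open, as does a single wrong label.

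The 1588 probe sets called between DPF and HG arrays were tested against other groupings. In a 2-group fit the real split gave 2228 calls, and the highest other of the 35 splits gave 0. The share of splits with as many calls was 0.0286, the smallest that 35 splits can give. The other splits also mix the 2 sources of hens on each side, so the count alone cannot exclude chance. Sequence variants under single probe sets may account for part of the 1588. Of the uncalled other probe sets of called genes 74.4% went in the called direction (95% bootstrap interval 71.6 to 77.1%, 995 probe sets), against 58.5% among 2346 uncalled pairs. The 74.4% lies between the bounds set for and against. Other probe sets that were called themselves were left out, which can lower the share, so it decides nothing. A stronger 3' bias of the DPF RNA could give part of the calls. Within 1316 genes the probe sets from predicted transcripts lay below those from cDNA by a median of -0.158 (95% bootstrap interval -0.19 to -0.122) in DPF against HG. In DPF+ against DPF- that median was -0.066 (95% bootstrap interval -0.085 to -0.041). With the 3' minus 5' difference as a covariate the calls ended (0) because the SE grew. The median absolute log2 change of the 1588 went from 0.893 to 1.37 and the median SE from 0.172 to 0.769. The difference between the sources of hens stays open and untested, as does a separate hybridization or normalization of the DPF and HG arrays. The labels and processing notes do not say whether the arrays were handled apart. The blank values divided by source, with 6 probe sets blank on the 4 DPF arrays and 2 on the 4 HG arrays. How this arose is not known.

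The lower antigen presentation genes in DPF+ could reflect fewer leukocytes in those samples. Outside the antigen presentation list only 1 leukocyte gene passed the filter, LSP1P1, which had a log2 change of 0.58 (limma adjusted p = 0.862), against the direction that fewer leukocytes would give. One gene near the filter value is too few to decide, and the 44 leukocyte probe sets had a median level of 2.48. Dependence on 1 array was also tested, and in 2 of the 4 fits without a DPF array the list's adjusted p was above 5% (0.749 without DPF+ replicate 2 and 0.540 without DPF- replicate 2). A difference between the selected lines in these genes stays open and was not tested.

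Neighbouring genes were not called together more often than chance gives for DPF against HG, the only contrast with calls. For DPF against HG, 25 adjacent pairs of 6957 were called in the same direction, against 25.6 ± 4.82 (SD) in permutations (permutation p = 0.583), and at an unadjusted p under 0.01 it was 41 against 41.4 ± 6.06 (permutation p = 0.549). For DPF+ against DPF- there were 0 pairs among 0 calls, and 1 pair among 92 genes at an unadjusted p under 0.01 (permutation p = 0.449). For HG+ against HG- and for the difference between the contrasts there were 0 calls, and 4 and 39 genes at an unadjusted p under 0.01. Both gave 0 pairs at either threshold. At the second, the permutations gave means of 7e-04 and 0.114 pairs, so these 2 contrasts decide nothing.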
